A study of Mus musculus with 6 samples.

How the data were processed

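Bone marrow cells of WT and Dnmt3a knockout mice were grown in medium with 10% fetal bovine serum, IL3 and SCF, and RNA was taken at week 1, per the labels' protocols. Libraries were made from mRNA selected with oligo(dT) and sequenced on an Illumina HiSeq instrument, per the labels' protocols. Whether the kit marked strand is not given in the sources used here, so reads of overlapping antisense genes may not have been told apart. The submitters' processing notes name HISAT, StringTie 1.2.1, edgeR and the mouse build mm10, with no role or order. The aligner's settings, the gene annotation and the counting rules are not given in the sources used here.

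The deposited table holds 1 row per gene and 1 column of FPKM per library, rounded to 2 decimals, per the file headers. It has 15139 rows, of which 14639 carry a gene number and 500 are unnamed gene models. Of the gene numbers, 14603 matched the GRCm38.p6 annotation, which gave names, positions and gene types. Symbols turned into dates by a spreadsheet were restored from the gene number for 23 rows. No row has a group mean of 0 in either genotype, so genes detected in 1 genotype alone are not seen, and 1659 rows hold a 0 in at least 1 library. No mitochondrial gene is in the table. Besides FPKM, the authors deposited a signed fold (a score equal to the ratio of the group means within a relative tolerance of 0.001), an unadjusted p-value, and a p-value, adjusted p-value, log fold change and log mean level of a second test. The input of that second test and the base of its logs are not given in the sources used here. The authors' log fold change, deposited as a score, has the sign opposite to their signed fold for 84.1% of genes. With its sign reversed, it had a slope of 0.259 on the log2 change over the genes called here. The authors' log fold change is therefore not used here as a measure of size.

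The labels name 2 groups of 3 samples. The WT group has 3 columns. The Dnmt3a knockout group has 2, of replicates 2 and 3, and its replicate 1 was not analysed here. The labels give the genotype of the knockout as both knockout and knockdown in different fields, and the analysis follows the titles. The labels do not say that replicates came from separate animals or cultures. Sex-linked genes show that WT replicate 1 came from another animal than WT replicates 2 and 3. The p-values measure the spread between these samples, which may be in part technical. No pair of libraries was near-identical: the median absolute log2 difference between libraries of 1 group was 0.0936 to 0.140. FPKM carry no read totals, and their low values did not reveal whole reads, so the depth of each library and its counting error are unknown. FPKM summed to between 560387 and 604368 per library, and between 11038 and 11090 genes had at least 1 FPKM.

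The test fixed before the data were examined was a quasi-likelihood test on read counts with edgeR, which was not run because the deposited values are FPKM. The choice written then for other units was limma on log values. Accordingly, limma 3.58.1 in R 4.3.3 was used on log2(FPKM + 1), with a mean-variance trend and empirical Bayes moderation, genotype as the only term and 3 residual degrees of freedom. Genes were tested if at least 2 libraries reached 1 FPKM, and p-values were adjusted by Benjamini-Hochberg over all 11365 tested genes, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, knockout over WT, which understates the change of low genes. An exact permutation of 3 against 2 libraries has 10 splits and cannot give a two-sided p under 0.2, so no single gene was tested that way. In all, 51.1% of tested genes had both knockout libraries on 1 side of all WT libraries, against an average of 20% over the 10 splits. Genes can move together, so the share in 1 split can lie far from that average for reasons other than genotype. The 51.1% is therefore a description and not a test.

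The procedure was tested on simulated data built from the real means, with 10 runs of 198 changed genes. It recovered 36.1% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 91.5% of those changed 4-fold. Of its calls, 4.6% were false. The simulated noise was normal on the log2 scale, independent between genes and equally wide in both groups, as limma assumes. Changed genes were drawn above a floor of expression in WT and were far fewer than those called in the real data. The rates hold under these settings and do not measure false calls in the real comparison.

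There were 26 gene lists of 528 genes fixed before the data were examined, from textbook markers and pathways. The 22 with at least 3 tested genes, leaving out the sex-linked one, were tested with camera in limma at a preset correlation of 0.01 between genes, two-sided and adjusted over the 22 lists. With that setting 12 lists passed, 5 upward and 7 downward, while none passed with an estimated correlation (2 at an unadjusted p under 0.05), and 13 passed with fry. The mitochondrial list has no gene in the table, and the sex-linked list served only to read the sex of each library. The cell type lists describe genes in mixed cells and do not count cells.

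Genes named in the text followed a rule fixed before the data were examined. It took Dnmt3a, the 12 largest rises and 12 largest falls among called genes with both knockout libraries on 1 side of WT and a mean of at least 5 FPKM in the higher group, and every called PI3K gene. It also took up to 4 called members of each list with the smallest p, or 6 in the mast cell, neutrophil and monocyte lists, or the 2 with the smallest p where none was called. Predicted genes, Rik clones and names of pseudogenes were left out of the largest changes. Some genes that the rule took or that a list holds are not reported here. Other genes named as examples were chosen after their values were seen. Leaving out each library, other scalings, filters, pseudocounts and variance models, the replicate number as a block and sex as a covariate were tried as alternatives. Figures and further tests used Python 3.11.15 with scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.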

Results

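Messenger RNA was sequenced from mouse bone marrow cells kept for 1 week with interleukin 3 (IL3, 10 ng/ml) and stem cell factor (SCF, 50 ng/ml), a cytokine pair that supports immature myeloid cells and mast cells. The marrow came from wild-type (WT) mice and from mice in which Dnmt3a, a de novo DNA methyltransferase, had been deleted. The labels name Mx-Cre, a recombinase used for deletion in blood cells, for both genotypes. WT was measured in 3 libraries. Of the 3 Dnmt3a knockout (KO) samples, replicates 2 and 3 were analysed, and replicate 1 was not analysed here. Levels are given as FPKM, the fragments of a gene scaled to its length and to all mapped fragments, so that the sequencing depth of each library is unknown. The question posed by the series was how loss of Dnmt3a alters myeloid cells, with the PI3K pathway named in its title.

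Dnmt3a (gene 13435), on chromosome 12 from 3801559 to 3914443 in GRCm38.p6, was lower in both knockout libraries than in every WT library. Its level was 6.68, 9.99 and 9.04 FPKM in WT replicates 1, 2 and 3, and 2.58 and 3.42 FPKM in KO replicates 2 and 3. The mean fell from 8.57 ± 1.70 FPKM (SD, n = 3) to 3.0 ± 0.594 FPKM (SD, n = 2), a log2 change of -1.25 ± 0.17 (SE; limma adjusted p = 0.00279). FPKM do not show which exons carried the remaining reads, and the exons removed are not given in the sources used here. Among the other genes of DNA methylation, the maintenance enzyme Dnmt1 (log2 change -0.08, adjusted p = 0.637), Dnmt3b (-0.06, 0.808) and the demethylase Tet2 (0.17, 0.344) did not pass the test. Idh1, which makes the co-substrate of the Tet enzymes, fell by 0.78 on the log2 scale, Idh2 by 0.42 and the DNA glycosylase Tdg by 0.32. With Dnmt3a itself, these were the 4 of 17 tested genes of that list that passed, over all genes and adjusted over the list alone. The list as a whole did not pass (camera adjusted p = 0.280). Tdg lost its call with sex as a covariate (adjusted p = 0.262) and without WT replicate 1, 2 or 3 or KO replicate 3 (0.0803, 0.148, 0.0947 and 0.159). It was also lost under median-of-ratios, upper-quartile and total scaling (0.0891, 0.116 and 0.0631), quantile normalization (0.114), without the filter on low genes (0.0597) and without the mean-variance trend (0.0694).

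The genotypes differed in the expression of many genes. Of 11365 genes tested, 2507 changed, with 1032 higher and 1475 lower in the knockout (limma, adjusted p under 0.05). A change of at least 2-fold was found for 530 of them, 201 higher and 329 lower. Without WT replicate 2 the number changed was 1623. The largest rises that the fixed naming rule took included the immediate early transcription factors Fosb (log2 change 2.56 ± 0.25 SE), Egr3 (2.30 ± 0.35), Nr4a1 (2.23 ± 0.14) and Egr1 (2.05 ± 0.18). They also included Sapcd1 (2.48), Rps4l (2.26), Galnt18 (2.21), the serine protease gene Klk8 (2.17), the tetraspanin gene Tspan8 (2.16), the glutamate receptor subunit gene Grin2c (2.11) and Ccdc80 (2.07). Rps4l is annotated as a transcribed pseudogene of a ribosomal protein gene, and its reads can be shared with its relatives, so its level is uncertain. The largest falls were led by the MHC class II genes H2-Aa (-3.30 ± 0.34), H2-Eb1 (-3.24 ± 0.27), Cd74 (-3.02 ± 0.26) and H2-Ab1 (-2.98 ± 0.28). Pltp (-2.92), the lectin gene Mgl2 (-2.86), Saa3 (-2.80), the fibronectin gene Fn1 (-2.70), Fcrls (-2.50), Olfm1 (-2.43) and Pld4 (-2.43) also fell. These 22 genes had limma adjusted p values between 0.000236 and 0.00396. Eif3j1, a subunit gene of a translation initiation factor, fell by 3.28 ± 0.87 (adjusted p = 0.0358), but WT replicate 3 held 1.85 FPKM against 23.7 FPKM in WT replicates 1 and 2, and its reads can be shared with the paralog Eif3j2. Its call was lost when any library other than WT replicate 3 was left out (adjusted p = 0.0750 to 0.146), without the filter on low genes (0.0669), without the mean-variance trend (0.0527) and with robust variances (0.156).

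Xist and the Y-linked genes showed that sex was not balanced. WT replicates 2 and 3 held 14.4 and 15.3 FPKM of Xist, the female-specific RNA of the inactive X. WT replicate 1 and both knockout libraries held 0 to 0.02 FPKM of Xist and 12.98, 14.1 and 14.8 FPKM of the Y-linked Ddx3y. With sex as a covariate, which compares the knockout libraries with WT replicate 1, 1312 genes changed, 520 higher and 792 lower, and 1230 of them were also called without it. The split between higher and lower calls also moved with scaling: after upper-quartile scaling 1294 genes (53.8% of calls) were higher, against 41.2% without it. The first principal component of the 500 most variable genes held 79.0% of their variance and placed the knockout libraries at 16.5 and 22.8 and the WT libraries between -15.7 and -11.6. WT libraries correlated at 0.994 to 0.995 with each other across genes and at 0.977 to 0.985 with knockout libraries, and the knockout pair at 0.993 (Pearson's r; genes are not independent replicates).

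**Figure D1:**
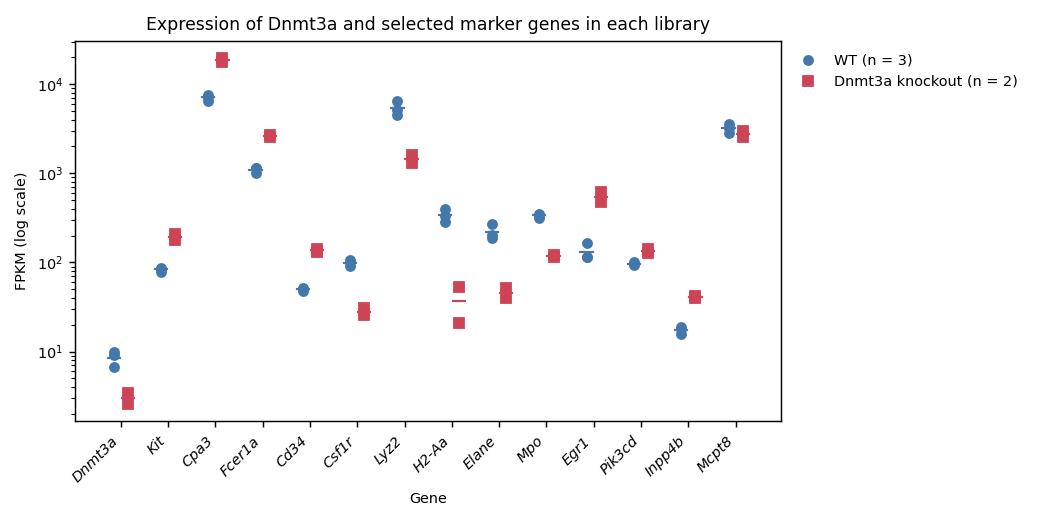
FPKM on a log scale of Dnmt3a and 13 other genes in each library, with a circle for each of the 3 WT libraries, a square for each of the 2 knockout libraries and a dash for each group mean. The knockout libraries lie below WT for Dnmt3a, Csf1r, Lyz2, H2-Aa, Elane and Mpo and above WT for Kit, Cpa3, Fcer1a, Cd34, Egr1, Pik3cd and Inpp4b, while those of Mcpt8 overlap with WT.

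Genes of the PI3K, AKT and mTOR pathway moved in both directions. Of 37 tested genes, 3 rose and 6 fell (4 and 6 adjusted over the list alone). Inpp4b, a phosphatase that acts on PI3K lipid products, rose from 17.5 ± 1.42 FPKM (SD, n = 3) to 40.8 ± 1.21 FPKM (SD, n = 2), a log2 change of 1.18 ± 0.09. Pik3cd, the catalytic subunit p110δ found mainly in blood cells, rose by 0.47 ± 0.08, and Inpp5d, which encodes the lipid phosphatase SHIP1, by 0.44 ± 0.08. The PI3Kγ regulatory subunit genes Pik3r5 and Pik3r6 fell by 1.05 ± 0.09 and 0.60 ± 0.12 on the log2 scale, the adaptor gene Pik3ap1 by 0.97 ± 0.10 and the catalytic subunit gene Pik3cb by 0.47 ± 0.08. Pik3c2a, of the class II enzymes, fell by 0.58 ± 0.13 and Eif4ebp1, a translation repressor and target of mTOR, by 0.48 ± 0.09. The limma adjusted p values of these 9 genes lay between 0.000350 and 0.0173. Akt1 (log2 change -0.14, adjusted p = 0.264), Mtor (-0.07, 0.763) and Pik3ca (0.22, 0.164) did not pass. The list did not stand apart from other genes (camera adjusted p = 0.802, and 0.928 with an estimated correlation), with a median log2 change of -0.01 and a mean of -0.04 against an upward camera direction. The sign of that median turned positive under median-of-ratios, upper-quartile and total scaling. The fry test in limma gave a p of 5.72e-05 for changes in either direction and an adjusted p of 0.469 for a shift on balance. The first value does not compare the list with other genes, of which many changed (2507 of 11365 tested). The same fry p was 9.71e-08 for erythroid, 0.000195 for DNA methylation, 0.000874 for imprinted and 0.397 for eosinophil genes. It therefore does not set the PI3K list apart. Inpp5d and Pik3c2a lost their calls with sex as a covariate (adjusted p = 0.0891 and 0.134), and Pik3c2a also without WT replicate 2 (0.0600) or KO replicate 2 (0.0679).

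**Figure D2:**
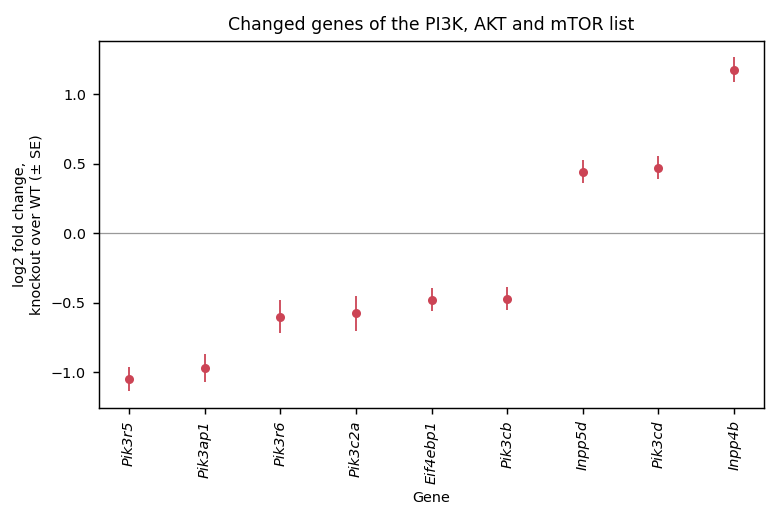
The log2 change from WT to knockout, on the log2(FPKM + 1) scale, of the 9 genes of the PI3K, AKT and mTOR list with an adjusted p under 0.05, ordered by change, with bars of 1 SE. They run from Pik3r5 at -1.05 to Inpp4b at 1.18, with 6 below 0 and 3 above.

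Most mast cell genes rose. Of 20 tested, 13 rose and 1 fell (14 and 1 adjusted over the list alone), with a median log2 change of 0.89 (camera adjusted p = 1.36e-09; adjusted p = 0.393 with an estimated correlation). Kit, the receptor for SCF, rose from 83.5 ± 4.64 FPKM (SD, n = 3) to 195 ± 22.2 FPKM (SD, n = 2), a log2 change of 1.21 ± 0.09. Fcer1a, a subunit of the IgE receptor, rose by 1.25 ± 0.10, the tryptase gene Tpsb2 by 1.30 ± 0.13, and Il1rl1, the receptor for IL33, by 1.28 ± 0.08. The amine transporter gene Slc18a2 rose by 1.26 ± 0.09 and Rab27b, of granule transport, by 0.90 ± 0.08. Carboxypeptidase A3, Cpa3, rose from 7120 to 18600 FPKM, and it was the gene with the highest level in both knockout libraries. The chymase gene Cma1 (0.35, adjusted p = 0.471) and the histamine-forming enzyme gene Hdc (-0.10, 0.449) did not pass. The member that fell was Ctsg (-0.63), which is also in the neutrophil list. Of 10 basophil genes, 6 rose and none fell, over all genes and adjusted over the list alone, with a median of 0.55 (camera adjusted p = 0.000272; adjusted p = 0.393 with an estimated correlation). Gzmb (1.27), Cd200r3 (1.01), Cyp11a1 (0.68) and Fcer1a, which is also in the mast cell list, were among them. The basophil proteases Mcpt8 (3219 FPKM in WT and 2763 FPKM in the knockout, adjusted p = 0.306) and Prss34 (1869 and 1764 FPKM, 0.862) did not pass. Against the male library WT replicate 1 alone, the medians were 0.87 for the mast cell and 0.49 for the basophil genes.

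Most monocyte and macrophage genes fell. Of 28 tested, 24 fell and 1 rose, over all genes and adjusted over the list alone, with a median log2 change of -1.39 (camera adjusted p = 6.46e-13; adjusted p = 0.393 with an estimated correlation). Csf1r, the receptor for macrophage colony-stimulating factor, fell from 99.2 ± 7.58 FPKM (SD, n = 3) to 28.1 ± 3.78 FPKM (SD, n = 2), a log2 change of -1.79 ± 0.11. Trem2, a lipid receptor of macrophages, fell by 2.10 ± 0.15, the transcription factor gene Klf4 by 1.80 ± 0.10, F13a1 by 1.30 ± 0.09 and the lysosomal Cd68 by 1.24 ± 0.09. Lysozyme, Lyz2, fell from 5392 to 1449 FPKM. The fractalkine receptor gene Cx3cr1 was the member that rose, by 1.41 ± 0.10, and Adgre1 (-0.05, adjusted p = 0.801), Ly6c2 (-0.04, 0.833) and Apoe (-0.23, 0.558) did not pass. Of 12 genes of dendritic cells and MHC class II, 10 fell and none rose, over all genes and adjusted over the list alone, with a median of -1.73 (camera adjusted p = 1.44e-07; adjusted p = 0.393 with an estimated correlation). H2-DMa, which helps to load peptide, fell by 2.27 ± 0.16 and Ciita, the transactivator of class II genes, by 1.69 ± 0.14. Against WT replicate 1 alone, the medians were -1.33 and -1.75.

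Most neutrophil genes fell as well. Of 21 tested, 14 fell and none rose (16 and 0 adjusted over the list alone), with a median log2 change of -0.82 (camera adjusted p = 1.00e-06; adjusted p = 0.424 with an estimated correlation). Neutrophil elastase, Elane, fell from 220 ± 42.4 FPKM (SD, n = 3) to 45.8 ± 7.67 FPKM (SD, n = 2), a log2 change of -2.23 ± 0.17. Myeloperoxidase, Mpo, fell by 1.51 ± 0.08, Chil3 by 1.49 ± 0.18, proteinase 3, Prtn3, by 1.46 ± 0.19 and Fcnb by 1.43 ± 0.17. The receptor for granulocyte colony-stimulating factor, Csf3r, fell by 0.87 ± 0.16. S100a9, which had the highest level of all genes in each WT library, fell from 10760 to 6059 FPKM. Cebpe (-0.13, adjusted p = 0.476), Cxcr2 (-0.07, 0.580) and Padi4 (0.11, 0.586) did not pass. Against WT replicate 1 alone, the median was -1.07. That library had the highest neutrophil genes of the WT group, with a median difference from the WT mean of 0.30, against -0.07 and -0.19 in WT replicates 2 and 3.

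**Figure D3:**
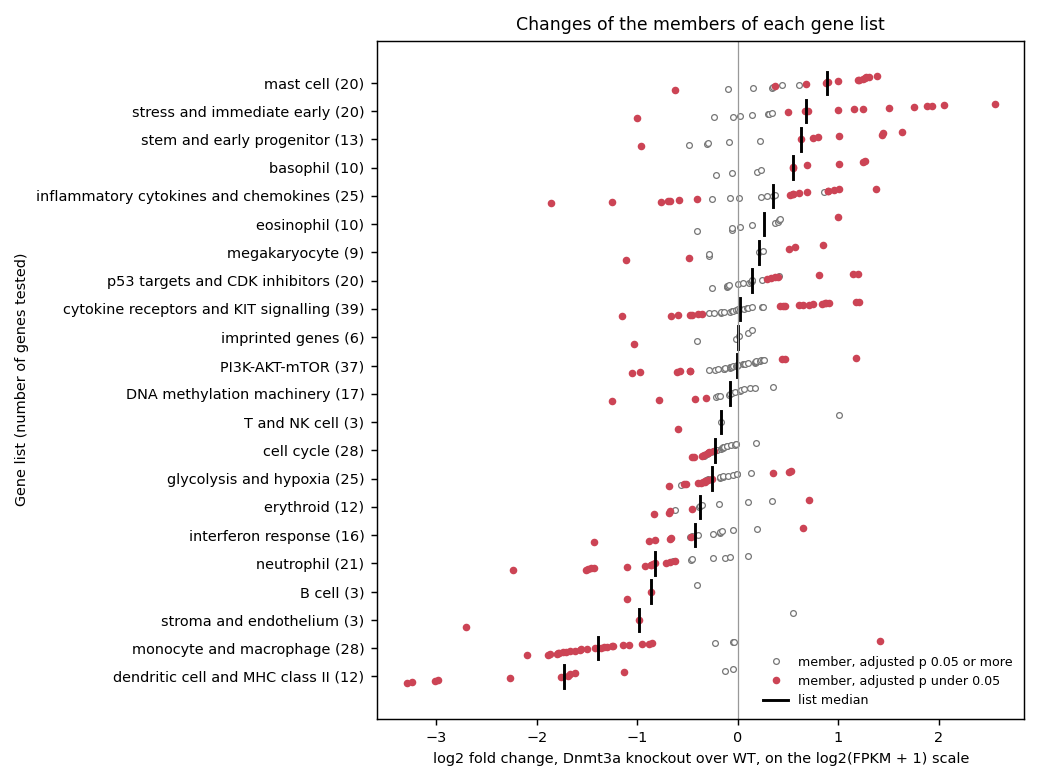
The log2 change from WT to knockout of each tested gene, on the log2(FPKM + 1) scale, for the 22 lists with at least 3 tested genes, with the number tested in brackets, filled circles for an adjusted p under 0.05 and a bar at the list median. Medians run from -1.73 for dendritic cell and MHC class II genes to 0.89 for mast cell genes.

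Several genes of stem cells and early progenitors rose, 7 of 13 tested, and 1 fell (8 and 2 adjusted over the list alone; median log2 change 0.63; camera adjusted p = 0.00978; adjusted p = 0.393 with an estimated correlation). Cd34, a surface marker of progenitors and of mast cells, rose from 49.8 ± 2.32 FPKM (SD, n = 3) to 136 ± 5.62 FPKM (SD, n = 2). The transcription factor genes Gata3 and Meis1 rose by log2 changes of 1.45 ± 0.14 and 1.01 ± 0.12 and the surface antigen gene Ly6a by 1.64, while Lmo2, a cofactor of early blood transcription, fell by 0.97 ± 0.08. The list lost its call without KO replicate 2 or 3 (adjusted p = 0.0695 and 0.0785), with medians of 0.25 and 0.19, where Gata3 and Nr4a2 no longer passed the filter on low genes. Without that filter it passed with a median of 0.07. Of the Hoxa and Meis1 list, 2 genes were tested, and Meis1 rose and Pbx3 did not pass (0.32, adjusted p = 0.191).

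Genes of other lineages were tested as well. Of 10 eosinophil genes, 1 rose, over all genes and adjusted over the list alone: the chemokine receptor gene Ccr3, by 1.00 ± 0.24. The major granule genes Prg2 (5382 FPKM in WT and 7090 FPKM in the knockout, adjusted p = 0.191) and Epx (579 and 563 FPKM, 0.869) did not pass. The eosinophil list did not pass (median 0.26, camera adjusted p = 0.137), but it did without WT replicate 3 (0.0232) or KO replicate 2 (0.0154) and with sex as a covariate (0.000291), where its median was 0.69. That last call rests on WT replicate 1 alone, whose median difference from the WT mean over these genes was -0.37, against 0.06 and 0.28 in WT replicates 2 and 3 and 0.02 and 0.44 in KO replicates 2 and 3. Of 12 erythroid genes, 1 rose and 4 fell, over all genes and adjusted over the list alone. The riser was Gata1 (0.71), a factor also of mast cells and megakaryocytes, and Hba-a1 (-0.84), Klf1 (-0.67) and Car2 (-0.46) were among those that fell (list median -0.38, camera adjusted p = 0.240). Of 9 megakaryocyte genes, 3 rose, Gp1ba (0.85), Itga2b (0.57) and Itgb3 (0.51), and 2 fell, Pf4 (-1.11) and Vwf (-0.49), the same counts as adjusted over the list alone (median 0.21, camera adjusted p = 0.297, and 0.0476 without KO replicate 2). Of 3 B cell genes tested, Blnk (-1.10) and Il7r (-0.86) fell (3 fell adjusted over the list alone; median -0.86; camera adjusted p = 0.0374; adjusted p = 0.449 with an estimated correlation). Of 3 genes of T and NK cells, Nkg7 fell by 0.59 (1 rose and 1 fell adjusted over the list alone; median -0.16; camera adjusted p = 0.802). Of 3 genes of stroma and endothelium, Fn1 and Acta2 (-0.99), which macrophages and smooth muscle also express, fell (1 rose and 2 fell adjusted over the list alone; median -0.99; camera adjusted p = 0.190). The B cell list lost its call with sex as a covariate (adjusted p = 0.0593, median -0.47), without KO replicate 3 (0.104, -0.88) and without the filter on low genes (0.172, -0.41). With sex as a covariate the calls of Hba-a1, Klf1, Itga2b, Gp1ba and Il7r were lost (adjusted p = 0.0525 to 0.0966). Without KO replicate 3, the calls of Ccr3, Hba-a1, Car2, Itgb3, Il7r and Nkg7 were lost (adjusted p = 0.157, 0.0516, 0.156, 0.0635, 0.0790 and 0.0558). Car2 also lost its call without any other library (0.0573 to 0.0838), under median-of-ratios, upper-quartile and quantile scaling (0.0646, 0.0697 and 0.0655), without the filter (0.0725) and without the mean-variance trend (0.0542). Ccr3 lost its call without WT replicate 2 (0.0650) or the filter (0.0516), and Il7r without WT replicate 3 (0.0538) or KO replicate 2 (0.0702).

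In the list of stress and immediate early genes, 12 of 20 rose and 1 fell (14 and 1 adjusted over the list alone), with a median log2 change of 0.68 (camera adjusted p = 2.03e-07; adjusted p = 0.393 with an estimated correlation). Ier2 rose from 118 ± 11.0 FPKM (SD, n = 3) to 460 ± 114 FPKM (SD, n = 2), Ier3 by a log2 change of 1.15 ± 0.12, and Fos and Jun by 1.88 and 1.75. Atf3, an immediate early factor of the stress response, fell by 1.01, and the chaperone genes Hspa8 (-0.05) and Hsp90aa1 (0.02) did not pass. Genes of cytokine receptors and KIT signalling changed in both directions, 13 higher and 7 lower of 39 (13 and 8 adjusted over the list alone; median 0.02; camera adjusted p = 0.0584). Besides Kit, the phospholipase gene Plcg1 rose by 1.18 ± 0.10 and the IL3 receptor gene Il3ra by 0.74 ± 0.07, while Csf2ra, the receptor for GM-CSF, fell by 1.16 ± 0.10. The STAT5 target genes Cish and Socs2 both rose by 0.87. This list passed without WT replicate 2 or 3 or KO replicate 2 (adjusted p = 0.0388, 0.0379 and 0.0130) and with sex as a covariate (0.0276). Of 25 genes of inflammatory cytokines and chemokines, 10 rose and 7 fell (13 and 7 adjusted over the list alone; median 0.35; camera adjusted p = 0.0605, and 0.0213 without WT replicate 3). The interleukin 6 family genes Lif and Osm rose by 1.38 ± 0.16 and 0.89 ± 0.12. The chemokine genes Ccl17 and Ccl22, made by dendritic cells and macrophages, fell by 1.25 ± 0.12 and 1.86, and the NF-κB inhibitor gene Nfkbia by 0.76 ± 0.09.

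Of 28 cell cycle genes tested, 8 fell and none rose (14 and 0 adjusted over the list alone; median log2 change -0.23; camera adjusted p = 0.000666; adjusted p = 0.482 with an estimated correlation). Plk1 fell by 0.43 ± 0.08 and Cdt1 by 0.45 ± 0.09, and the proliferation marker gene Mki67 did not pass (-0.17, adjusted p = 0.151). Of 20 p53 targets and CDK inhibitors, 7 rose and none fell, over all genes and adjusted over the list alone (median 0.14; camera adjusted p = 0.00337; adjusted p = 0.449 with an estimated correlation). By directional fry the list did not pass (adjusted p = 0.0600). The CDK inhibitor gene Cdkn1a rose from 198 ± 7.30 FPKM (SD, n = 3) to 348 ± 35.6 FPKM (SD, n = 2), Gdf15 from 11.8 to 28.2 FPKM, and Eda2r, on the X chromosome, by a log2 change of 1.15 ± 0.22. The p53 list lost its call without KO replicate 3 (adjusted p = 0.0785), where its median was 0.04, and Eda2r and Cdt1 lost theirs with sex as a covariate (0.0841 and 0.0597). Of 16 interferon-stimulated genes, 6 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.43; camera adjusted p = 0.0122; adjusted p = 0.449 with an estimated correlation). Oas1a fell by 1.43 ± 0.12, Ifit2 by 0.83 ± 0.16 (adjusted p = 0.0513 without KO replicate 2) and Irf7 by 0.67 ± 0.11, and Usp18 rose by 0.65. The interferon list did not pass among genes of at least 5 FPKM (adjusted p = 0.308, median -0.18).

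In the list of glycolysis and hypoxia, 3 of 25 genes rose and 10 fell (3 and 13 adjusted over the list alone; median log2 change -0.26; camera adjusted p = 0.0203; adjusted p = 0.393 with an estimated correlation). The glycolytic enzyme genes Pgam1 and Pfkl fell by 0.36 ± 0.08 and 0.33 ± 0.07, and the oxygen sensor gene Egln3 by 0.69 ± 0.08. The vascular growth factor gene Vegfa rose by 0.53, and Ldha did not pass (-0.15, adjusted p = 0.385). The calls of Pgam1 and Pfkl were lost with sex as a covariate (adjusted p = 0.155 and 0.112) and without WT replicate 2 (0.0723 and 0.0695) or 3 (0.0783 and 0.0553). With the replicate number as a block they were lost too (0.0608 and 0.0653), as was that of the list (camera adjusted p = 0.0730, median -0.24). Of 6 imprinted genes tested, Igf2r fell by 1.03 ± 0.13 and the other 5 did not pass, over all genes and adjusted over the list alone (camera adjusted p = 0.671). Of the germline genes, which DNA methylation silences in body cells, 2 were tested, Piwil2 (-0.52, adjusted p = 0.0579, but 0.0305 without the filter and 0.0217 without the mean-variance trend) and Sycp3 (0.22, 0.372). Neither passed over all genes, while 1 fell adjusted over the list alone. Only 8 of the 24 germline genes had deposited values. Genes with a mean of 0 in either genotype are absent, so a germline gene silent in WT and expressed in the knockout could not be seen.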

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

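Alternative pseudocounts, the 5 FPKM filter, quantile normalization, the other variance models, the sex covariate, chromosomes X and Y left out, the test against a minimum change and the crossed block were chosen after seeing the data. DESeq2, limma-voom, edgeR's robust fit, glmTreat and the 50-count filter need counts and were not run; nor were transcript rows or the fit without Dnmt3a_KO replicate 1. No named gene or list that passed changed direction. The majority of calls did turn from lower to higher after upper-quartile scaling (1294 higher, 1109 lower) and quantile normalization (1216 and 1196), against 1032 and 1475, and the medians of lists that did not pass (PI3K, imprinted, stroma, megakaryocyte and cytokine receptor genes) changed sign in some alternatives. The count of changed genes, 2507, was 1312 with sex as a covariate (which compares the knockout with WT replicate 1; the cause was not tested) and 970 when tested against a 1.2-fold change (a stricter null). Leaving out 1 library gave 1623 (without WT replicate 2) to 2659 changed genes and 435 to 617 at least 2-fold; a lone knockout library was then assumed to vary like WT. At least 2-fold changes numbered 805 with a pseudocount of 0.1, which shrinks low genes less, against 530. Other scalings, filters and variance models gave 2071 to 2545 changed genes. Dnmt3a stayed lower with an adjusted p of 0.000760 to 0.0180 in each alternative for which its fit was kept (not the 1.2-fold test or the blocks without WT replicate 1), and the PI3K list passed in none of those, nor by camera with an estimated correlation or by directional fry. With an estimated correlation 0 of 22 lists passed by camera, the lowest adjusted p being 0.393, since that setting allows for genes of a list moving together. The first component held 71.5% of the variance over all tested genes; the cause was not tested. The replicate number shared by 2 libraries of each genotype gave, as a block, 2058 changed genes, 571 of at least 2-fold, with 1 residual degree of freedom. WT replicate 1 shares its number with no other library analysed, so the block compares female WT with male knockout libraries. The fit without WT replicate 1 does the same, and the Y-linked Ddx3y was called in both with a log2 change of 3.93. These fits therefore do not separate genotype from sex. Differences between replicates 2 and 3 correlated at 0.0421 across genes between genotypes. That gave no sign of pairing, but 1 such correlation cannot exclude a shared day or batch. Of 107 named genes, 90 kept their side of the threshold with sex as a covariate, and 94 to 98 of the 104 to 107 still tested did so in each fit without 1 library. Among lists, fry lost p53 targets and gained erythroid and stroma genes. Cytokine receptor genes passed after total scaling, quantile normalization or the 5 FPKM filter, and the block gained inflammatory genes and lost glycolysis genes. The block lost Tdg (adjusted p = 0.0571), Car2 (0.0912), Pgam1 (0.0608) and Pfkl (0.0653). Depth is unknown, so its effect was not assessed.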

Other observations

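The tests given here were chosen after results were seen, except the first of genes near Eif3j1 and that near Dnmt3a, whose predictions came before their outcome. Annotation terms in the deposited table were tested for genes changed at least 2-fold, against the 10066 tested genes with a term (1449 terms of 10 to 500 genes, one-sided Fisher's exact test, adjusted over terms). Among the lower genes 48 terms passed. Defense response held 27 genes where 5.07 were drawn by chance (adjusted p = 1.15e-09). Antigen processing of exogenous peptide held 8 of its 14 genes, among them the H2-DM genes and Unc93b1, which carries nucleic acid sensors. Carbohydrate binding held 14 genes, among them the C-type lectins Mgl2, Clec10a, Clec4n and Clec4d. Phagocytosis held 9 of 35, with Mertk, Axl, Clec7a and Abca1. Response to interferon-beta held 6 of 16, which were the HIN-200 family genes Ifi203, Ifi204, Mnda, Mndal and Pyhin1 and AI607873, while 3 others of the 16 (Gbp6, Gbp4 and Tgtp2) rose at least 2-fold (adjusted p = 0.186 among the higher genes). Among the higher genes 8 terms passed, with cell surface at 13 genes where 3.15 were drawn by chance (adjusted p = 0.00752; Il2ra, Icos, Cd69, Kit), proteolysis at 8 of 89 and response to calcium ion at 5 of 25. Cell surface passed among the lower genes too, with 19 genes where 5.25 were drawn by chance (adjusted p = 0.000164). Many terms share genes and the terms are not independent.

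The authors' deposited table lists 922 genes at an adjusted p under 0.05, 437 with a positive and 485 with a negative signed fold. Of the 920 tested here, 893 were also called here. The signed fold is the ratio of the same FPKM means, so agreement in direction carries no information, and the authors' deposited log fold change had the sign opposite to it for 100% of their calls. A further 1614 genes were called here alone and 27 in the authors' deposited table alone. Kit, with an adjusted p of 0.167 in the authors' deposited table, was among those called here alone (limma adjusted p = 0.000382). So were the PI3K genes Pik3cb, Pik3c2a, Pik3cd, Inpp5d and Eif4ebp1 (authors' adjusted p = 0.186, 0.524, 0.806, 0.817 and 0.962). Inpp4b, Pik3r5, Pik3ap1 and Pik3r6 were called in both. Mpo, Prtn3 and Cd68 were called here alone too (authors' adjusted p = 0.230, 0.163 and 0.137), while Elane, Csf1r and Trem2 were called in both.

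Mast cell genes were higher and monocyte, macrophage and MHC class II genes lower in the knockout. Sex of the libraries as the whole cause is argued against by the difference from the male WT replicate 1. The knockout libraries differed from it by medians of 0.87 for 20 mast cell genes and -1.33 for 28 monocyte and macrophage genes. For the 12 genes of the dendritic cell and MHC class II list the median was -1.75. A loss of macrophage-like and neutrophil-like cells alone would raise mast cell and eosinophil genes alike. The mast cell median exceeded the eosinophil median by 0.63 against all WT libraries (permutation p = 0.0176 over 30 genes) but by 0.18 against WT replicate 1 alone (permutation p = 0.316), the WT library with the lowest eosinophil genes. Erythroid genes, which would rise as well, had a median of -0.38. The mast cell median exceeded theirs by 1.26 (permutation p adjusted over 4 lists = 0.00032 over 32 genes), and by 1.31 against WT replicate 1 alone (0.00152). Megakaryocyte genes also lay below mast cell genes, by 0.68 (0.0225) and 0.78 (0.0229). Basophil genes did not differ past the threshold (0.33, adjusted p = 0.355, and 0.50, 0.248), though the abundant Mcpt8 (-0.22) and Prss34 (-0.06) were not called. The permutations shuffle genes between lists, so their p values do not measure the spread between libraries. Genes of a list can move together: their estimated correlation was 0.937 for eosinophil, 0.603 for megakaryocyte, 0.135 for mast cell and -0.07 for erythroid genes. The comparison with WT replicate 1 rests on that library alone. Within these limits, the erythroid and megakaryocyte medians count against such a loss alone. Among genes of at least 5 FPKM, where 5 erythroid genes are left, the erythroid difference was 1.25 and 1.30, but its adjusted p was 0.0602 and 0.0524, and none of the other lists passed either. A loss of these cells alone is therefore left open, and it cannot be told apart from a gain of mast cells. Changed expression within 1 cell type stays open too, and an effect of the genotype was not tested apart from these.

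Of the 20 tested genes in the fixed list of stress and immediate early genes, 12 were higher in the knockout, with the Fos, Jun and Egr genes among them, while the immediate early gene Atf3 was lower. No list of immediate early genes alone was fixed. Stress during handling would be expected to raise the other stress genes of the list as well. Their median log2 change was 0.15 over 9 genes with Atf3 and 0.23 over 8 without it, and they went both ways, which leaves it open. More signalling through ERK would raise its output genes outside that list. Of 15 such genes, 7 rose, among them Phlda1 (1.97), Dusp5 (1.77), Dusp4 (1.23) and Spry2 (0.91), and Plaur and Ccnd1 fell, while Spry2 and Dusp6 are also in the list of KIT signalling (camera p = 0.000448, and p = 0.210 with an estimated correlation). ERK signalling may contribute, but bulk libraries do not measure the mix of cells, so it cannot be told apart from a different mix.

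Eif3j1 (chromosome 2, 122028580 to 122053632) and its close paralog Eif3j2 (chromosome 18, 43475418 to 43477836) went in opposite directions. WT replicates 1 and 2 held 23.7 FPKM of Eif3j1 and 14.5 and 15.5 of Eif3j2, while WT replicate 3 held 1.85 and 36.1, and the knockout libraries 0.28 and 0.20 against 39.6 and 39.4. The sum of both differed by at most 1.05 times between the 5 libraries, which is consistent with the same reads being assigned to one gene or the other. A candidate explanation for the change of assignment is a block of DNA from another mouse strain on chromosome 2 in WT replicate 3 and the knockout libraries. Within 10 Mb of Eif3j1, 6 of 158 genes (3.80%) were shifted in WT replicate 3 by at least 0.5 towards the knockout, against 1.15% elsewhere (one-sided Fisher's exact p = 0.0113). In 2 of the 6, the overlapping genes Ubox5 and Fastkd5, the knockout libraries did not both share the shift: Fastkd5 held 0.27 FPKM in WT replicate 3 and 2.54 and 1.02 in the knockout libraries. In the other 4 (Gpr176, Gchfr, Jmjd7 and Bmf) both knockout libraries were shifted by at least 0.5 in the same direction, or 2.53% against 0.44% elsewhere (one-sided Fisher's exact p = 0.00641). Gpr176 held 9.44, 7.56 and 13.51 FPKM in WT replicates 1, 2 and 3 but 40.05 and 37.43 in the knockout libraries, well beyond WT replicate 3. Gchfr held 7.93 FPKM in WT replicate 3 and 9.57 and 7.53 in the knockout libraries. Jmjd7 and Bmf are low genes, with at most 2.32 FPKM in any library. The block is a candidate that few genes support, and strain genotypes were not analysed here.

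DNA carried along with the Dnmt3a allele from the strain in which it was made was tested as a source of changed genes. Within 10 Mb of Dnmt3a, 4 of 31 tested genes changed (Sdc1, Fkbp1b, Ncoa1 and Rhob), or 12.9%, against 22.3% elsewhere (one-sided Fisher's exact p = 0.938). An excess near the locus was not seen. With 31 genes, the window could hold only a small part of the 2507 calls whatever the outcome. The test therefore does not bear on whether such DNA was a large source. It could not exclude single genes, and DNA beyond 10 Mb was not tested.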
